A study of Mus musculus with 30 samples.

How the data were processed

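The study measured messenger RNA by sequencing in brown adipose tissue (BAT), liver and sWAT, the usual abbreviation of subcutaneous white adipose tissue, of C57BL/6N mice. Per the labels, the libraries of each tissue came from mice given HFD, the usual abbreviation of high-fat diet, or HFD with imeglimin, an oral glucose-lowering drug. The 30 libraries form 6 groups of 5, and the same 10 numbers recur in the 3 tissues. The design text of the series states 4 against 4, whereas the labels give 5 in every group, and the labels were followed. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

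Per the labels' protocols, total RNA was extracted, poly(A) RNA was selected and strand-specific libraries were prepared with NEB kits. Per the submitters' processing notes, STAR and RSEM were used with the mouse genome build GRCm39. Their versions, the annotation release and any filters are not given in the sources used here. The authors deposited TPM, a unit that divides estimated counts by transcript length and scales each library to the same total. Each of the 30 columns summed to 1000000 over the 55357 genes listed. TPM keeps no record of sequencing depth, so the depth of each library is unknown and no counting interval is given. No 2 columns were identical, and the highest correlation between libraries was 0.995. All sample columns of the deposited TPM table were used. Gene symbols, identifiers and coordinates were taken from the deposited TPM table, where 79 symbols are carried by more than 1 gene identifier.

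Because a TPM value is a share of the library total, abundant transcripts set the scale for all others. The table lists 37 mitochondrially encoded genes. A search of GENCODE vM21 transcripts, used for their sequence only, with BLAST+ 2.17.0 for transcripts with at least 90% identity over at least 80% of their length found 16 nuclear near-copies of mitochondrial transcripts, 6 of them above 1 TPM on average. The share of the total held by both kinds, and by each kind, was computed for each library. Reads of a mitochondrial transcript and of its nuclear copy may be divided between them by the authors' quantification, so values of single members are uncertain, and the same holds for ribosomal protein genes with pseudogenes and for the Mup, Gstm, Serpina3 and Cyp2c families.

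Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1, and the other steps used Python 3.11.15. Fold changes refer to this scale, which understates the change of genes with low TPM. In each tissue, genes with at least 1 TPM in at least 5 of the 10 libraries were tested with limma's moderated test with a trended variance, imeglimin minus HFD, two-sided, with Benjamini-Hochberg adjustment at a threshold of 0.05. Each tissue was fitted alone. Differences between tissues in the response were tested as an interaction in a fit of all 30 libraries over genes with at least 1 TPM in at least 5 libraries. Gene lists, 38 in number, covered lipid, glucose and mitochondrial metabolism, stress and immune responses and cell types. They were tested with camera at its preset correlation of 0.01 where at least 5 members were measured, beside camera with an estimated correlation and fry. Camera compares a list with all other genes, whereas the fry p-value asks whether the members of a list move, on balance, one way. Members past the threshold were counted over all genes tested and again after adjusting over the list alone. A small set of index genes per tissue was tested with exact two-sided permutation tests, which reach 0.00794 at the lowest with 5 against 5. After adjustment over the index genes of a tissue, a single gene at that value could not pass, so a lack of calls there is weak evidence. Fold changes were correlated across genes between tissues, with p-values from all 126 splits of the 10 numbers into groups of 5. Groups, main tests, gene lists and alternatives were fixed before the data were examined, apart from the alternatives named as added later. The rules for reading the tests of explanations and the counts over other splits of the libraries were written after values had been seen.

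The genes named were chosen by a rule. In each tissue it takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 1 TPM. Where fewer than 5 passed, genes of lowest p were added up to 5, given as not passing. It also takes the index genes, up to 4 members of every list that passed or that held 3 or more members past the threshold, and the 5 genes of lowest p in each interaction. Predicted genes were counted but not named among the 10. Some genes that the rule names are not reported here.

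The steps were tested on simulated data, drawn from the mean and spread of each gene, in which 200 genes were shifted by known amounts. With the members of 1 list shifted by 0.50 instead, camera called that list and 0 others in each tissue. Genes were drawn independently here, whereas camera estimated correlations of 0.308 (lipogenesis) and 0.696 (ribosomal proteins) within lists in the real BAT libraries. The simulations therefore do not show how often camera calls lists of correlated members. The shares of false calls given below likewise hold for independent genes. In the BAT comparison, over 11402 genes, limma recovered 68.7% of shifts of 0.50 on the log2 scale, 94.0% of shifts of 1 and 97.0% of shifts of 2, with 1.70% of the calls false. In the liver comparison, over 11516 genes, it recovered 65.7%, 89.6% and 98.5%, with 2.87% false. In the sWAT comparison, over 13736 genes, it recovered 25.4%, 76.1% and 92.4%, with 5.15% false. In the interaction of BAT and liver, over 14953 genes, it recovered 13.4%, 70.1% and 92.4%, with 2.50% false. In that of BAT and sWAT it recovered 13.4%, 77.6% and 95.5%, with 21.5% false, and in that of liver and sWAT 19.4%, 77.6% and 97.0%, with 18.9% false. The excess of false calls lay in the comparisons with sWAT, whose libraries varied more, while all tissues shared 1 estimate of spread. Library weights per tissue scale the spread of all genes of a tissue alike. With them 9.74%, 19.9% and 17.8% of the calls were false in the 3 comparisons. A larger spread of sWAT for all genes alike thus does not account for the excess. A version with a separate spread per tissue was therefore added after the data were seen. Its false calls were 6.08%, 6.14% and 6.03% in the 3 comparisons, and it recovered 69.5%, 53.5% and 54.5% of all simulated shifts.

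The alternatives were a pseudocount of 0.10, no filter, a mean of at least 5 TPM, median-ratio scaling, removal of mitochondrially encoded genes, robust variances, array weights, a joint fit of all 30 libraries with and without the number as a block, the 20 libraries of a pair of tissues, and leaving out each number in turn. Added after the data were seen were removal of mitochondrially encoded genes together with their nuclear copies, fits without libraries rich in transcripts of other tissues, Acta1 as a covariate, the mean of the muscle list as a covariate of the lipogenesis list mean, library weights per tissue, and the counts adjusted over single lists under each alternative.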

Results

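RNA sequencing compared HFD mice with HFD mice given imeglimin in 3 tissues, BAT, liver and sWAT. The title of the series places the comparison in a study of systemic metabolism, BAT and the gut microbiota in obese mice. Each of the 6 groups held 5 libraries, and values were TPM, so the sequencing depth behind them is unknown. At least 1 TPM was reached by 11461 ± 246 genes in BAT with HFD and 11250 ± 271 with imeglimin (mean ± SD, n = 5). The corresponding numbers were 11553 ± 109 and 11486 ± 141 in liver, and 13698 ± 157 and 14041 ± 750 in sWAT. Ucp1, the uncoupling protein of brown fat, stood at 4863 ± 754 TPM in HFD BAT, against a mean of 0.141 TPM in HFD liver and 0.454 TPM in HFD sWAT. Alb, which encodes serum albumin, stood at 56440 ± 7537 TPM in HFD liver.

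Some libraries carried transcripts of other tissues. In BAT, the muscle actin gene Acta1 reached 1804 TPM in HFD replicate 79 and 1493 TPM in imeglimin replicate 94, against at most 192 TPM in the other 8 libraries. In sWAT, imeglimin replicate 88 held 589 TPM of the B cell gene Cd79a, against at most 2.28 TPM in the other 9, and 6876 TPM of Alb, against at most 354 TPM. Lep, the leptin gene of white adipocytes, stood at 1360 TPM in that library and at 3812 TPM or more in the other 9. Mitochondrially encoded transcripts and their nuclear copies made up 65.4% ± 1.84 of the TPM in HFD BAT and 68.2% ± 0.689 in imeglimin BAT (n = 5). That difference of 2.80 percentage points had an exact permutation p of 0.0238 and an adjusted p of 0.0714 over the 3 tissues, so it did not pass. Mitochondrially encoded transcripts alone had a difference of 0.163 percentage points (exact permutation p = 0.833), whereas the nuclear copies, tested alone after the data were seen, differed by 2.64 (exact permutation p = 0.00794, adjusted p = 0.0238), from 25.5 to 27.6% with HFD to 28.5 to 30.05% with imeglimin. In liver the share of both kinds was 21.0% in both groups, and in sWAT it was 20.5% ± 2.21 with HFD and 18.8% ± 1.15 with imeglimin, with exact permutation p-values of 0.960 and 0.175.

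**Figure D1:**
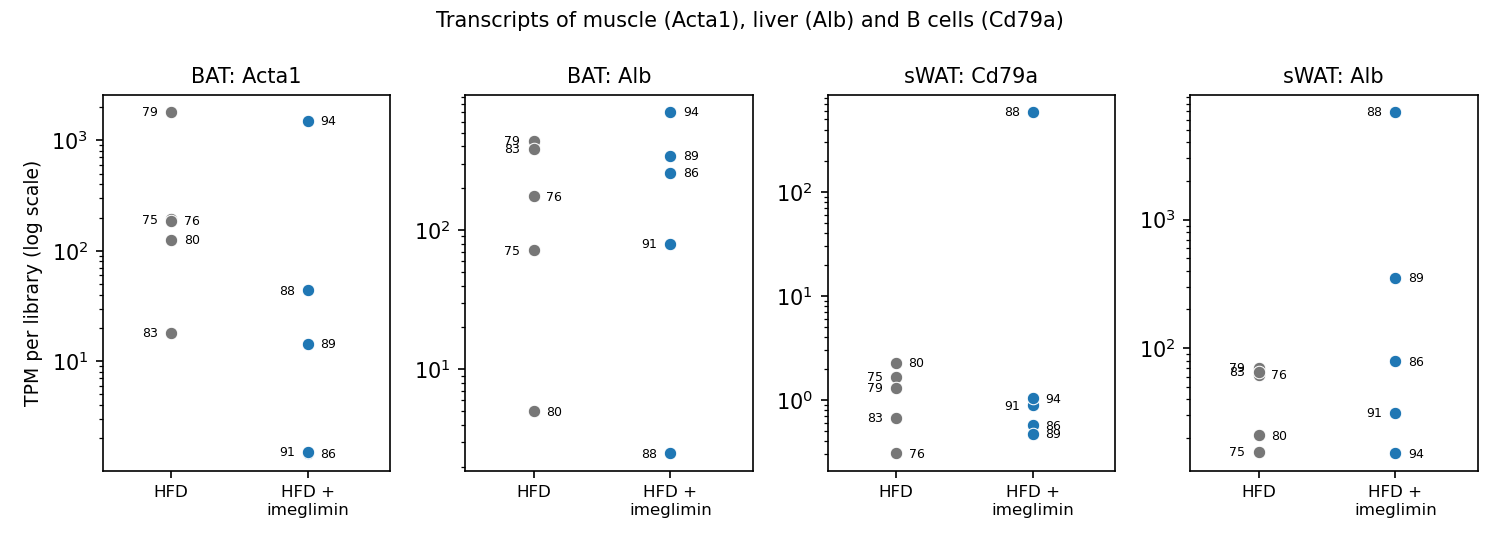
TPM per library on a log axis for Acta1 (muscle) and Alb (liver) in BAT and for Cd79a (B cells) and Alb in sWAT, with each point a library labelled by its replicate number, grey for HFD and blue for imeglimin. Acta1 reached 1804 and 1493 TPM in BAT replicates 79 and 94, and Cd79a 589 TPM in sWAT replicate 88.

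The first comparison asked which transcripts differed with imeglimin in BAT. The fatty acid synthesis genes Acly, Fasn and Scd2 were lower in every imeglimin library than in any HFD library. Acly, which makes cytosolic acetyl-CoA from citrate, fell by 1.85 on the log2 scale (SE 0.334, adjusted p = 0.0446), from 566 ± 167 to 167 ± 80.7 TPM (SD, n = 5). Fasn, the fatty acid synthase gene, fell by 1.64 (SE 0.301, adjusted p = 0.0446), from 1966 ± 509 to 669 ± 325 TPM. Scd2, a stearoyl-CoA desaturase gene, fell by 1.53 (SE 0.187, adjusted p = 0.0291), from 36.2 ± 8.38 to 11.96 ± 3.33 TPM. Among genes past the threshold the largest change was that of the fructose transporter gene Slc2a5, which fell by 2.04 (SE 0.283, adjusted p = 0.0324), from 8.58 ± 3.64 to 1.33 ± 0.882 TPM. In GRCm39, Acly lies on chromosome 11 at 100367179 to 100418826, Fasn on chromosome 11 at 120696672 to 120715373, Scd2 on chromosome 19 at 44282113 to 44295303, and Slc2a5 on chromosome 4 at 150203740 to 150228626.

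**Figure D2:**
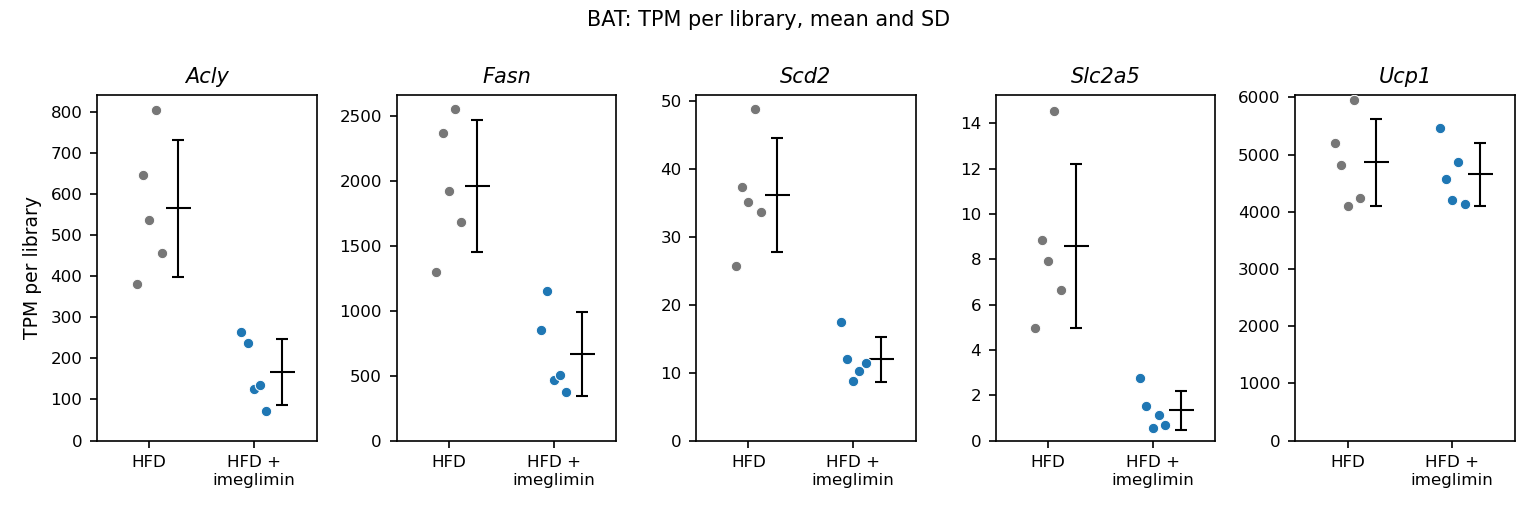
TPM per BAT library (points, grey for HFD and blue for imeglimin) of Acly, Fasn, Scd2, Slc2a5 and Ucp1, with the mean and SD of each group of 5 beside them on axes from 0. Acly, Fasn, Scd2 and Slc2a5 did not overlap between the groups, while Ucp1 stood at 4863 TPM with HFD and 4652 TPM with imeglimin.

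The other large falls were those of Acaca, which encodes acetyl-CoA carboxylase (fell by 1.496), the NADPH-producing malic enzyme gene Me1 (fell by 1.20), Sorcs2 (fell by 1.20), the fatty acid elongase gene Elovl6 (fell by 1.18) and Lctl (fell by 1.11), with adjusted p-values from 0.0291 (Me1) to 0.0485 (Elovl6). The 1 gene past the threshold in the other direction was Ddt, the D-dopachrome tautomerase gene, which rose by 0.36 (SE 0.0714, adjusted p = 0.0485), from 156 ± 13.3 to 201 ± 14.1 TPM. Scand1 (0.29, adjusted p = 0.0502), mt-Co3 (0.39, 0.0624, uncertain because of its nuclear copies), Apoc1 (0.50, 0.0627) and Rps28 (0.21, 0.0710) had the next lowest p among higher genes and did not pass.

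Of 11402 genes tested in BAT, 98 fell and 1 rose in limma's test, and the median size of the called changes was 0.526. At an unadjusted p under 0.05 there were 2627 lower and 143 higher genes, against 570 in all expected by chance. The groups did not overlap for 776 genes, 6.81% of those tested, where chance gives 0.794%. The median log2 fold change of all genes was -0.12, a shift that depends on scaling. Relative to it, Acly changed by -1.73, Fasn by -1.52, Scd2 by -1.41 and Ddt by 0.48. With median-ratio scaling, or without mitochondrial transcripts and their nuclear copies, 5 genes passed, and these were the same genes in both cases: Scd2, Me1, Deptor, Ccdc3 and Tulp4, all lower. Without muscle-rich replicates 79 and 94 there were 0 calls, and leaving out single libraries gave 0 (without 76, 79, 80, 89, 91 or 94), 37 (without 75), 136 (without 86), 205 (without 83) or 698 (without 88).

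Among the gene lists in BAT, lipogenesis and triglyceride synthesis held the most members past the threshold over all genes. Of its 26 measured members 10 fell over all genes tested, 16 when adjusted over the list alone, and 0 rose. Besides those above, Slc25a1, the mitochondrial citrate carrier gene, fell by 1.02 (SE 0.159, adjusted p = 0.0446), and Pgd and G6pdx of the pentose phosphate pathway fell by 0.87 and 0.61. Scd1 (-1.29, adjusted p = 0.0556) and Thrsp (-0.69, 0.0650) passed over the list alone, whereas the triglyceride-forming genes Dgat1 (0.02) and Dgat2 (0.00363) lay near 0. The list's median was -0.64, or -0.53 relative to all genes, and camera gave an adjusted p of 6.7e-08 (adjusted p = 0.659 with an estimated correlation). Its mean per library was 7.21 ± 0.175 with HFD and 6.53 ± 0.194 with imeglimin on the log2 scale (n = 5, exact permutation p = 0.00794, the smallest possible, and 0.0694 adjusted over the lists). The number of members that fell when adjusted over the list alone was 14 or more under every alternative run.

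**Figure D3:**
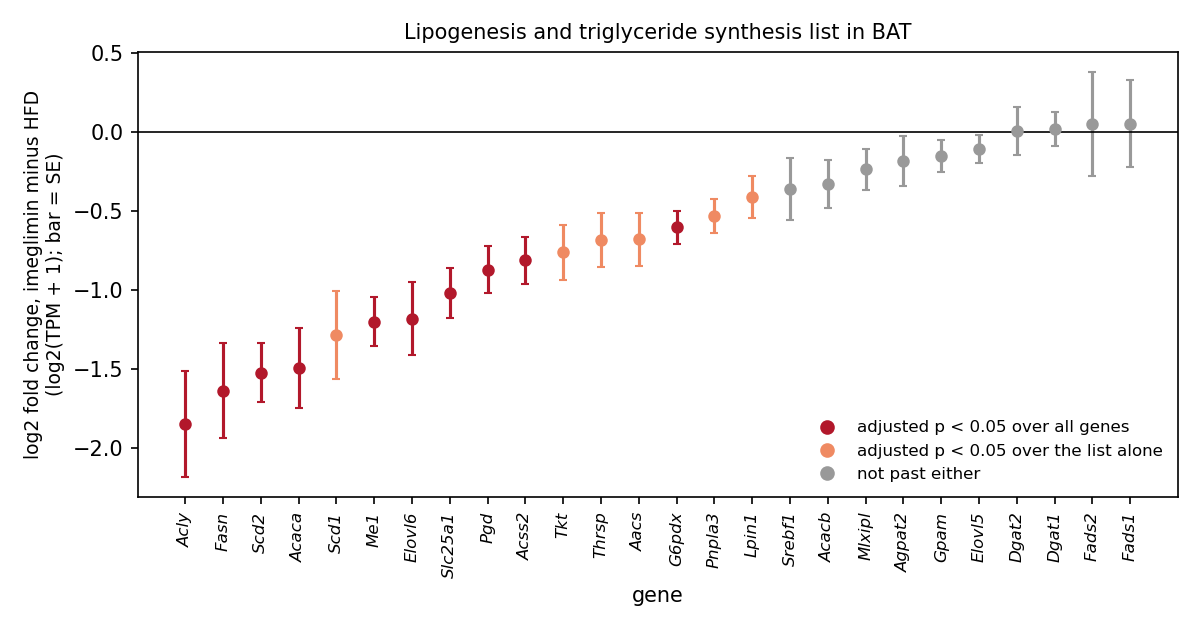
Log2 fold change in BAT, imeglimin minus HFD on log2(TPM + 1), of the 26 measured members of the lipogenesis and triglyceride synthesis list, ordered by size, with bars giving the SE (n = 5 per group). Dark red marks the 10 members that fell over all genes tested, orange those past the threshold over the list alone only, and grey the rest.

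Glycolytic genes formed the next group in BAT. Of 20 measured members of the glycolysis and glucose uptake list 4 fell over all genes and 14 when adjusted over the list alone. Gpi1 fell by 0.55, Pkm by 0.52, Aldoa by 0.51 and Gapdh by 0.50, each with an adjusted p of 0.0446 or, for Gapdh, 0.0464. The list median was -0.42, or -0.30 relative to all genes (camera adjusted p = 5.5e-07, adjusted p = 0.659 with an estimated correlation). The skeletal muscle list had 19 of 19 measured members with negative changes, a median of -1.86 and a camera adjusted p of 0.448 (adjusted p = 0.874 with an estimated correlation). Without the muscle-rich replicates 79 and 94 the glycolysis list had 16 members past the threshold over the list alone, but camera then called the muscle list lower (adjusted p = 1.3e-08), so this omission did not remove the difference in muscle transcripts. It was also called lower with median-ratio scaling (0.00137), with mitochondrial transcripts and copies removed (0.00131) and without 94 alone (3.2e-07). With median-ratio scaling the glycolysis number was 9.

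No member of the NRF2 antioxidant list (0 of 18) or of the cholesterol biosynthesis list (0 of 24) passed over all genes in limma's test, although 10 and 8 fell when adjusted over the list alone. Gsr, the glutathione reductase gene, changed by -0.33 (adjusted p = 0.0548), Osgin1 by -0.67, Txnrd1 by -0.30 and Ftl1 by -0.28. Sc5d (-0.72, adjusted p = 0.0556), Fdps (-0.39), Idi1 (-0.40) and Lss (-0.44) led the cholesterol list. The camera adjusted p was 0.00217 for NRF2 (adjusted p = 0.659 with an estimated correlation) and 0.00320 for cholesterol (adjusted p = 0.7999 with an estimated correlation). The NRF2 call was lost with median-ratio scaling and with mitochondrial transcripts and copies removed.

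Lists that camera placed above the other genes in BAT had small changes. Cytosolic ribosomal protein genes had a median of 0.09 with 49 of 53 members positive (adjusted p = 2.6e-22, adjusted p = 0.659 with an estimated correlation), led by Rps28, Rps27 (0.24), Rpl13a (0.18) and Rpl37 (0.14), none past the threshold. Nuclear genes of oxidative phosphorylation had a median of 0.03 and a mean of 0.00110 (adjusted p = 9.1e-09, adjusted p = 0.7999 with an estimated correlation). Within it Ndufs1 (-0.40), Uqcrc1 (-0.18) and Ndufa10 (-0.19) had negative changes and Ndufa5 (0.16) a positive one. The endothelial list, with a median of -0.03 and a mean of 0.00392, and the mitochondrially encoded list, with a median of -0.01 and a mean of -0.01, were called higher relative to all genes (adjusted p = 0.00758 and 0.0247, each with an adjusted p = 0.7999 with an estimated correlation). Vwf (-0.30) and Gpihbp1 (0.21) were endothelial members, and mt-Nd5 (-0.47) and mt-Nd3 (0.22) did not pass over all genes. The endothelial call was lost without replicate 75 or 91 and with median-ratio scaling, and the mitochondrially encoded one without 79, without 80 and without both 79 and 94.

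Liver-expressed genes were also called higher in BAT. The hepatocyte list had a median of 0.25 (camera adjusted p = 8.1e-05, adjusted p = 0.861 with an estimated correlation), with Cyp2e1 at 33.7 ± 25.1 TPM with HFD and 73.7 ± 62.5 TPM with imeglimin (n = 5), and Alb ranged from 2.50 to 703 TPM across the 10 libraries. Its mean per library was 3.98 ± 1.67 with HFD and 4.27 ± 1.95 with imeglimin on the log2 scale (n = 5, exact permutation p = 0.778). Whether liver RNA was carried along in the BAT libraries was not tested. The xenobiotic list (median 0.19, camera adjusted p = 0.00758, adjusted p = 0.7999 with an estimated correlation), the acute phase list (0.17, 0.00758, adjusted p = 0.867 with an estimated correlation) and the bile acid list (0.10, 0.0314, adjusted p = 0.7999 with an estimated correlation) also passed. Cyp2b10 changed by 0.95 and Alas1 by -0.31, Orm1 by -0.20, and Abcc4 by -0.28, none past the threshold. The interferon list (median 0.03, camera adjusted p = 6.0e-04, adjusted p = 0.7999 with an estimated correlation) included Ifi27l2a at 0.75. All 5 calls were lost with median-ratio scaling and with mitochondrial transcripts and copies removed. The hepatocyte call was also lost without replicate 80, and the xenobiotic one without 80, 89 or 94 and without both 79 and 94. The acute phase call was also lost without 80 or 94, and the bile acid one was lost in 10 of 14 settings.

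Of 35 lists tested in BAT, camera called 13, of which 9 were higher and 4 lower. With an estimated correlation 0 were called, and fry called 4, the lipogenesis (adjusted p = 0.00553), glycolysis (0.00553), NRF2 (0.00386) and cholesterol (0.0175) lists, all lower. Median-ratio scaling gave 3 higher and 5 lower lists, and the lower ones then included the macrophage and skeletal muscle lists. The macrophage list (median -0.36, 15 of 16 members negative, camera adjusted p = 0.207, adjusted p = 0.869 with an estimated correlation) was not called as reported here. It was called lower with median-ratio scaling (0.0144), with mitochondrial transcripts and copies removed (9.0e-04) and without replicate 75, 76 or 94.

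Thermogenic genes of BAT did not move one way as a group by camera or by fry (fry adjusted p = 0.349). The mixed version of fry, which asks whether members change in either direction, gave an adjusted p of 0.00833. Several other BAT lists passed that version too. Ucp1 stood at 4863 ± 754 TPM with HFD and 4652 ± 543 TPM with imeglimin (log2 fold change -0.06, SE 0.111, n = 5, exact permutation p = 0.675), and its sign turned to 0.09 with median-ratio scaling. Cidea, a lipid droplet gene, was higher in 5 of 5 imeglimin libraries than the HFD mean (0.18, exact permutation p = 0.0159, 0.0635 adjusted over the 8 index genes). Elovl3 (-0.69) had the same exact permutation p-values, and Ppargc1a (-0.32), Dio2 (-0.16), Adrb3 (-0.02), Prdm16 (0.00549) and Fgf21 (-0.58) had adjusted exact permutation p-values of 0.212 or more. The thermogenic list of 24 measured genes had a median of -0.13 and a mean of -0.19, against an upward sign in camera (adjusted p = 0.536). Its 1 member that fell over all genes was Acot11, an acyl-CoA thioesterase gene, by 1.04 (SE 0.187, adjusted p = 0.0446), and over the list alone 4 fell and Cidea rose.

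The second comparison asked the same question in liver, where no gene passed. Of 11516 genes tested, limma called 0, the lowest adjusted p was 0.805, and 484 genes had an unadjusted p under 0.05 (192 higher, 292 lower) against 576 expected by chance. Groups did not overlap for 80 genes, 0.695% against 0.794% by chance. The lowest p-values belonged to Apol9a (-0.50), Tsku (-0.77), Proca1 (-0.64), Wfdc2 (-0.68) and Ssna1 (-0.39) among lower genes and to Fnip1 (0.45), Gpx6 (0.89), Lin7a (0.28), Zfp871 (0.33) and Rsrp1 (0.28) among higher ones. Tsku, which encodes the secreted protein tsukushi, stood at 67.1 ± 15.2 TPM with HFD and 38.5 ± 5.31 TPM with imeglimin (n = 5, adjusted p = 0.805).

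No index gene of the liver passed. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 34.0 ± 9.11 TPM with HFD and 53.6 ± 22.9 TPM with imeglimin (log2 fold change 0.58, n = 5, exact permutation p = 0.0952, adjusted 0.952). Fasn (-0.49), Scd1 (-0.61), Srebf1 (-0.17), Fgf21 (-0.38), Cyp8b1 (-0.11), the gluconeogenic genes Pck1 (-0.05) and G6pc (-0.06), and Cyp4a14 (-0.02) had adjusted exact permutation p-values of 0.976. The lipogenesis list, with 0 members past the threshold even over the list alone, had a median of -0.17 and a camera adjusted p of 0.0971 (adjusted p = 0.889 with an estimated correlation). Camera called it lower without replicate 75 (0.0102), 79 (0.00724), 86 (0.00413) or 91 (0.0136).

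Of 34 lists tested in liver, camera called 5, and each call was lost with an estimated correlation and with fry. The acute phase list was higher (median 0.21, camera adjusted p = 5.5e-04, adjusted p = 0.889 with an estimated correlation), with Serpina3n at 0.61, Steap4 at 0.67, Serpina3m at 0.39 and Crp at 0.15. The xenobiotic list (0.15, 7.1e-04, adjusted p = 0.369 with an estimated correlation) included Fmo2 at 0.63, Cyp2e1 at 0.27 and Cyp2c54 at 0.33. The hepatocyte list was higher by a median of 0.07 (adjusted p = 0.0141, adjusted p = 0.364 with an estimated correlation), while its member Mup20, a major urinary protein gene, changed by -0.83. The interferon list was lower (-0.12, camera adjusted p = 0.0105, adjusted p = 0.889 with an estimated correlation), with Irf7 at -0.49, Oas1a at -0.52, Oasl1 at -0.42 and Bst2 at -0.20. The NRF2 list was lower (-0.07, camera adjusted p = 0.0141, adjusted p = 0.889 with an estimated correlation), with the glutathione transferase genes Gstp1 (-0.64), Gstm3 (-0.73) and Gstm1 (-0.35) and with Keap1 (-0.13). None of these genes passed over all genes tested or over its list alone. The interferon call was lost without replicate 83, 86 or 88, the NRF2 one without 75, 76, 88 or 94, the acute phase one without 89 and the hepatocyte one without 91.

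The third comparison addressed sWAT, where Pck1 and C2 rose. Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase, rose by 1.68 on the log2 scale (SE 0.204, adjusted p = 0.0356), from 472 ± 102.2 to 1525 ± 401 TPM (SD, n = 5). The complement gene C2 rose by 0.81 (SE 0.0982, adjusted p = 0.0356), from 27.7 ± 4.14 to 48.9 ± 2.16 TPM. Pck1 lies on chromosome 2 at 172994841 to 173001066 and C2 on chromosome 17 at 35081580 to 35117241 in GRCm39. Cfd, the gene of the adipokine adipsin, did not pass at 1.41 (SE 0.212, adjusted p = 0.0994), with 2945 ± 759 TPM for HFD and 7835 ± 1851 TPM for imeglimin. Prtn3 (1.498) and Phyhd1 (0.72) followed among higher genes, and Hapln4 (-1.18), C6 (-1.02), Gpr135 (-0.71), Bcl2l10 (-0.99) and Nsdhl (-0.94) had the lowest p among lower ones, with adjusted p-values from 0.0994 to 0.154.

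**Figure D4:**
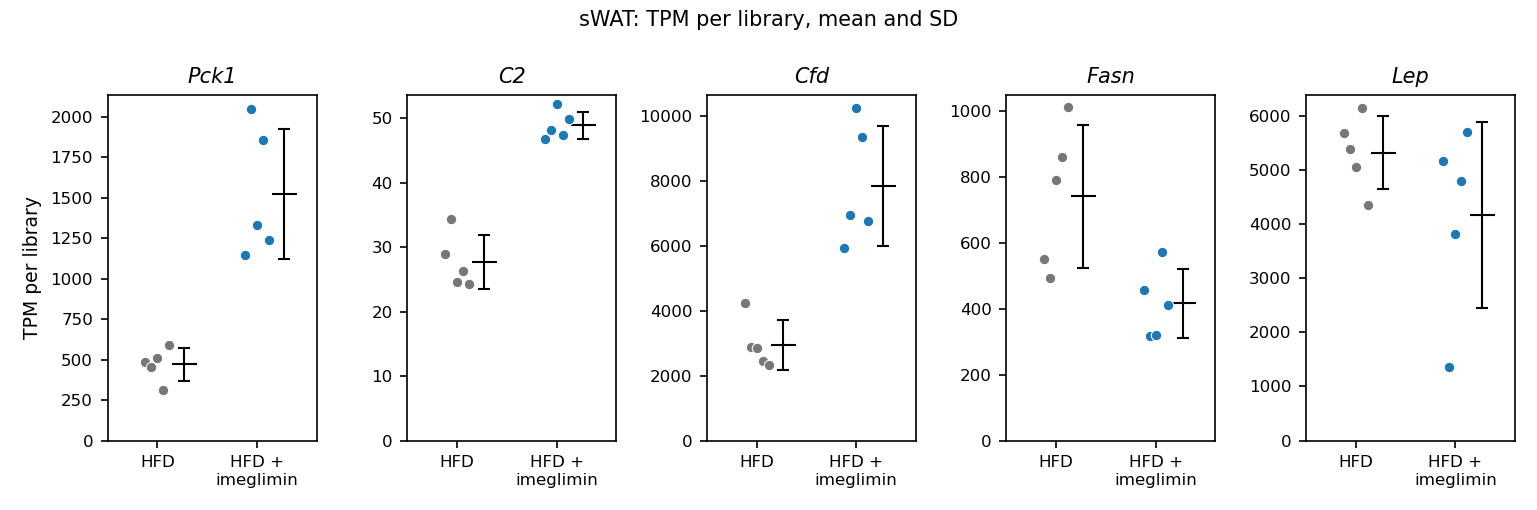
TPM per sWAT library (points, grey for HFD and blue for imeglimin) of Pck1, C2, Cfd, Fasn and Lep, with the mean and SD of each group of 5 beside them on axes from 0. Pck1 and C2 passed limma's test, and the lowest imeglimin value of Lep, 1360 TPM, belongs to replicate 88.

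Of 13736 genes tested in sWAT, 2 rose and 0 fell in limma's test, and 1558 had an unadjusted p under 0.05 (783 higher, 775 lower) against 687 expected by chance. Groups did not overlap for 419 genes, 3.05% against 0.794% by chance. Without replicate 88, which held the B cell and liver transcripts, 4 genes passed, Pck1, C2, Dock11 and Gm9696. Leaving out other libraries gave 0 calls (without 75, 79, 80, 89, 91 or 94), C2 alone (without 76), the adrenergic receptor gene Adrb3 alone (without 83), or Pck1 and Vnn1 (without 86).

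Cholesterol biosynthesis was the most clearly lower list in sWAT. Of its 24 measured members 0 passed over all genes in limma's test, 10 fell when adjusted over the list alone, and the median was -0.43 (camera adjusted p = 4.5e-10, adjusted p = 0.837 with an estimated correlation). Insig1, a sterol-responsive gene, changed by -1.15, from 408 ± 135 to 185 ± 62.3 TPM, Nsdhl by -0.94, Lss by -0.72 and Dhcr7 by -0.53. The list mean per library had an exact permutation p of 0.00794, the smallest possible, and an adjusted p of 0.196 over the lists. Since the first value cannot be lower, the second cannot measure the size of the fall. Without replicates 79, 80 or 89, 6 members passed over the list alone.

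The lipogenesis list in sWAT had 9 members lower and 1 higher when adjusted over the list alone, and none over all genes. Scd2 changed by -1.10, Acss2 by -0.91, Me1 by -0.87, Fasn by -0.82 and Acly by -0.42, whereas the desaturase gene Fads1 changed by 0.95. The list median was -0.16 and its mean -0.26 (camera adjusted p = 7.4e-05, adjusted p = 0.878 with an estimated correlation). Fasn stood at 742 ± 218 TPM with HFD and 416 ± 106 TPM with imeglimin (n = 5, exact permutation p = 0.0238, adjusted 0.190).

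Further lists were lower in sWAT by camera, each with an adjusted p = 0.878 with an estimated correlation. They were the endothelial list (median -0.31, camera adjusted p = 2.6e-06, 17 of 17 members negative, with Emcn at -0.66, Pecam1 at -0.28, Cdh5 at -0.44 and Tie1 at -0.40) and extracellular matrix (-0.32, 2.4e-05, with Lum at -1.17, Mmp14 at -0.51, Mmp2 at -0.47 and Col6a3 at -0.62). Cell cycle (-0.26, 0.00220, with Ccne1 at -0.68 and Cdk1 at -0.51), glycolysis (-0.16, 0.00470, with Aldoa at -0.46 and Tpi1 at -0.48), interferon response (-0.11, 0.00470, with Oasl2 at -0.60, Isg15 at -0.57 and Rsad2 at -0.74) and macrophages (-0.18, 0.0116, with Gpnmb at -1.35, Mmp12 at -1.34 and Trem2 at -1.06) were lower too. Called higher were ribosomal proteins (0.21, 1.4e-04), branched-chain amino acid catabolism (0.12, 0.00470, with Ivd at 0.34 and Hsd17b10 at 0.19) and the hepatocyte list (1.86, 0.0366), again each with an adjusted p = 0.878 with an estimated correlation. Replicate 88 held the highest values of Rps27 (1213 TPM) and Rps6 (1183 TPM) in its group, and without it the ribosomal, glycolysis and hepatocyte calls were lost. The hepatocyte call was also lost without 75, 76, 80 or 89 and with a pseudocount of 0.10. The macrophage call was lost without 83, 89 or 91, the branched-chain one without 76, 89 or 91 and with median-ratio scaling, and the cell cycle one without 89. Of 37 lists tested, camera called 11, 3 higher and 8 lower, while an estimated correlation and fry called 0.

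Index genes of sWAT did not pass. Lep (-0.50), Adipoq (-0.13), the macrophage gene Adgre1 (-0.48), Ccl2 (-0.31), Tnf (0.27) and Ppargc1a (0.31) had adjusted exact permutation p-values of 0.524 or more. Ucp1, at a mean of 0.454 TPM with HFD and 0.750 TPM with imeglimin, lay under the filter and had an exact permutation p of 0.492.

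**Figure D5:**
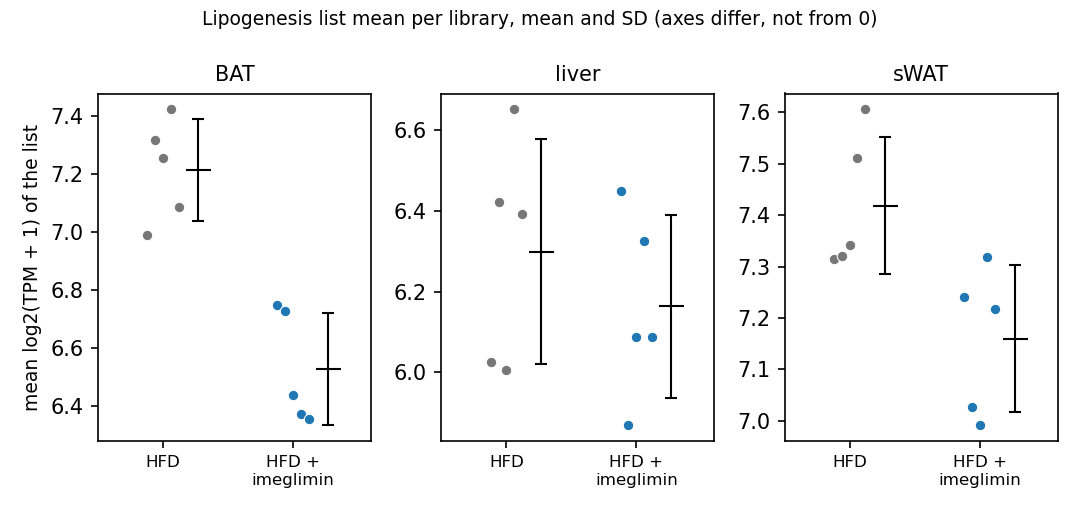
Mean log2(TPM + 1) of the lipogenesis and triglyceride synthesis list per library in BAT, liver and sWAT (points, grey for HFD and blue for imeglimin), with the mean and SD of each group of 5, on axes that differ and do not start at 0. In BAT the group means were 7.21 and 6.53, and the groups did not overlap.

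The last comparison asked whether the response to imeglimin differed between tissues. Deptor, which encodes an inhibitor of mTOR signalling, had log2 fold changes of -1.02 in BAT, 0.13 in liver and 0.11 in sWAT, a difference of -1.15 from liver (SE 0.171, adjusted p = 0.00253) and of -1.13 from sWAT (SE 0.171, adjusted p = 0.00339). Pygl, the glycogen phosphorylase gene, had log2 fold changes of -0.87 in BAT and 0.19 in sWAT, a difference of -1.06 (SE 0.176, adjusted p = 0.00535). Atp4b, at 1.74 ± 0.555 TPM in HFD BAT and 0.275 ± 0.263 TPM in imeglimin BAT, reached 1 TPM in 0 libraries of the other tissues, so its difference of -1.10 in both comparisons is its change in BAT alone. Tulp4 (-0.62) and Ube2n (-0.43) differed between BAT and liver, and Gm5182 (-1.45), which reached 1 TPM in 4 of 10 sWAT libraries, between BAT and sWAT. Between liver and sWAT the genes of lowest p were Gpx3 (-0.28 in liver and 1.35 in sWAT), Gm9696, Proca1, Gm44386 and Cetn4, with adjusted p-values from 0.0218 to 0.0238, but Gm9696, Gm44386 and Cetn4 reached 1 TPM in 0 liver libraries.

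Of 14953 genes tested, 25 differed between BAT and liver (24 with the lower change in BAT), 306 between BAT and sWAT (269 with the lower change in BAT) and 19 between liver and sWAT (9 with the lower change in liver). Of these, 19, 261 and 7 genes passed the expression filter in both tissues. With simulated data 21.5% of the calls between BAT and sWAT and 18.9% of those between liver and sWAT were false, against 2.50% between BAT and liver. With a separate spread per tissue, 2, 55 and 0 genes differed. Deptor passed that version in both comparisons (adjusted p = 0.0145 and 0.0220), as did Tulp4 (0.0219) and, between BAT and sWAT, Atp4b (0.0412), Gm5182 (0.0412) and Pygl (0.0461). Ube2n and Atp4b against liver (both 0.0794), and the 5 genes between liver and sWAT (0.222 or more) did not. Without BAT replicates 79 and 94 there were 0, 60 and 12 calls. Leaving out a single number in all tissues gave 0 to 193, 23 to 867 and 0 to 89 calls. With median-ratio scaling, the change in BAT was the lower one for 6 of 9 genes against liver and for 37 of 78 against sWAT, and that in liver for 4 of 12.

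Across genes, which are not independent replicates, correlations of fold changes between tissues were small. Pearson's r was 0.0523 between BAT and liver over 10091 genes (Spearman's rho -0.0189), 0.229 between BAT and sWAT over 11075 genes (0.142) and 0.111 between liver and sWAT over 10624 genes (0.122). Permutation p-values over the 126 splits of the 10 numbers were 0.738, 0.254 and 0.183, or 0.738, 0.381 and 0.381 adjusted over the 3 relations, so none passed. The median r over these splits was 0.0955, 0.00155 and 0.0556, so the value for BAT and liver lay below its median.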

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

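The tests of explanations in this part were chosen after the results were seen. Among 348 groups of 5 values looked at, 29 held a library apart from the others, 8.33% where chance marks about 1 in 20 groups (5%), and 10 of the 29 were sWAT replicate 88.

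The lower lipogenic transcripts of imeglimin BAT were the first pattern weighed, and a larger mitochondrial share of the TPM could lower all other genes. Without mitochondrial transcripts and copies the exact permutation p of the list mean per library was 0.00794 (two-sided). That is the smallest possible value, so it cannot show a weakening. The list median was then still -0.53, so a larger mitochondrial share does not account for the fall as the whole cause. Muscle carried along does not account for it as the whole cause either, since with the mean of the muscle list as a covariate the difference of list means was -0.71 (SE 0.135) and the slope on muscle -0.01 (SE 0.0298), where 0.375 would be needed. A loss of brown adipocytes, judged by the thermogenic list (median -0.13), does not account for it as the whole cause either. Of the 24 measured members of that list 16 were below 0 (exact permutation p of the list mean = 0.111), so such a loss as a part was not excluded. A response larger in BAT than in the other tissues was compared over the splits of the 10 numbers, of which a share of 0.0119 gave a difference from liver as low and 0.0198 a difference from sWAT as low (one-sided). The differences of list means were -0.56 (exact permutation p = 0.0238, two-sided) and -0.43 (0.0397). These values were not corrected for the median change of all genes, which was -0.12 in BAT, -0.00949 in liver and 0.0360 in sWAT. The list was also singled out for its fall in BAT, a choice that favours a larger difference there. A treatment response remains a hypothesis that these data do not rule out.

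The second pattern was sWAT imeglimin replicate 88. Lymph node tissue may have been in the sample, since 85.7% of B and T cell markers (17 of 18 and 19 of 24) were at least 4 times the highest of the other 9 libraries. Liver RNA may have been in it too, since 94 abundant liver-specific transcripts stood at a median of 12.1% of their liver level (quartiles 9.98% and 13.7%). How either came into the library was not tested, and no biological explanation was tested.

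The third pattern was the muscle transcripts of BAT replicates 79 and 94, a library from each group. Of 24 muscle markers 95.8% were at least 4 times higher in both than in any of the other 8, by a median of 6.80 times. Skeletal muscle dissected with the tissue could account for this, and no biological explanation was tested. Among the other 8 libraries Acta1 stood at 18.2 to 192 TPM with HFD and at 1.46 to 43.8 TPM with imeglimin. Apart from replicates 79 and 94, this muscle transcript was thus mostly lower with imeglimin.

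In sWAT imeglimin replicate 88, the values apart were 1360 TPM for Lep, 2950 for Adipoq, 20.8 for Ccl2, 157 for Cdh5, 574 for Rplp2, 1213 for Rps27, 340 for Rpl37, 1183 for Rps6 and 69.5 for Dbt, and 15355 genes reached 1 TPM. In imeglimin sWAT, Isg15 stood at 22.6 TPM in replicate 89. In HFD sWAT, Hapln4 stood at 5.27 TPM in replicate 75, C6 at 48.3 in 76, Dhcr7 at 11.4 in 79, Ifi44 at 3.22 in 80 and Pecam1 at 134 in 83. In HFD BAT, Apoc1 stood at 412 TPM and mt-Nd3 at 29602 in replicate 83, Rps28 at 46.8 and Tap1 at 2.33 in 76, and 11896 genes reached 1 TPM in 79. In imeglimin BAT, Gsr stood at 10.04 TPM in replicate 89, Sc5d at 21.2 in 86, Vwf at 2.51 in 94, and mt-Nd5 at 6988 and mt-Nd2 at 30209 in 91. In liver, Proca1 stood at 3.20 TPM in imeglimin replicate 86, and Ssna1 at 21.4 and Irf7 at 17.6 in HFD replicate 83.

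Responses that differed between tissues by the interaction test numbered 25 between BAT and liver, 306 between BAT and sWAT and 19 between liver and sWAT. The differences of BAT from liver were -1.10 for Atp4b, -1.15 for Deptor, -0.62 for Tulp4 and -0.43 for Ube2n. Those of BAT from sWAT were -1.10 for Atp4b, -1.13 for Deptor, -1.45 for Gm5182 and -1.06 for Pygl, and those of liver from sWAT -1.63 for Gpx3, 1.85 for Gm9696, -0.81 for Proca1, -1.79 for Gm44386 and -0.81 for Cetn4. Atp4b in liver and sWAT, and Gm9696, Gm44386 and Cetn4 in liver, reached 1 TPM in 0 libraries, so for these 4 the difference restates the value of 1 tissue. Gm5182 reached 1 TPM in 4 of 10 sWAT libraries, under the filter.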

How the results depend on the processing

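Depth is not given in TPM, so its effect on these results could not be examined, and with 5 libraries per group a single library can move a count. For each value below that left its call, grew or turned, the cause was not tested unless the alternative tests fewer samples or genes. Removal of mitochondrial genes with their nuclear copies, omission of muscle-rich or lymphocyte-rich libraries, Acta1 as a covariate, library weights and separate spreads per tissue, and counts over single lists were chosen after the data were seen.

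The count of genes changed by imeglimin in BAT, 99 as reported, was 0 with no filter, 331 (324 lower) with a mean of at least 5 TPM, 5 with median-ratio scaling, 228 (224 lower) without mitochondrially encoded genes and 5 without these and their nuclear copies. It was 709 (690 lower) with array weights, 398 (395 lower) with all 30 libraries in 1 fit, 392 with the number as a random replicate block, 0 without replicates 79 and 94 and 0 with Acta1 as a covariate. Leaving out single libraries gave 0 to 698. Among genes changed by imeglimin in liver, 0 as reported and 0 to 0 without single libraries, 2 passed with all 30 libraries in 1 fit and 2 with the random replicate block, Gpx6 and Proca1 both times. Among genes changed by imeglimin in sWAT, 2 as reported, there were 0 with no filter, 1 with median-ratio scaling, 1 without mitochondrially encoded genes and 1 without these and their copies, C2 each time. There were 22 with array weights, 553 with all 30 libraries in 1 fit, 549 with the random replicate block, 4 without replicate 88, and 0 to 4 without single libraries. Fits of all 30 libraries shared 1 spread over tissues, although the median residual SD was 0.244 in sWAT, 0.159 in BAT and 0.169 in liver. With simulated data, such a shared spread gave 21.5% and 18.9% false calls in the interactions with sWAT. The false share of the joint fit within a tissue was not simulated.

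The gene lists moved by imeglimin in BAT, 13 as reported, numbered 0 with an estimated correlation, 4 with fry, 8 (3 higher, 5 lower) with median-ratio scaling, 8 (3 higher, 5 lower) without mitochondrial genes and copies, and 10 to 17 without single libraries. In BAT the lipogenesis, glycolysis, cholesterol, ribosomal and oxidative phosphorylation calls were kept under all 14 settings that used the preset correlation. The gene lists moved by imeglimin in liver, 5 as reported, numbered 0 with an estimated correlation and 0 with fry, and 5 to 10 without single libraries (10 without 94, 9 without 75 or 80, 8 without 79 or 86). The gene lists moved by imeglimin in sWAT, 11 as reported, numbered 0 with an estimated correlation and 0 with fry, and 9 to 12 without single libraries. The count of lipogenesis members lower in BAT, adjusted over the list alone, was 14 to 18 over all settings and 16 to 18 without single libraries. The count of glycolysis members lower in BAT, adjusted over the list alone, fell to 9 with median-ratio scaling and was 14 to 16 without single libraries. The count of cholesterol members lower in sWAT, adjusted over the list alone, was 6 to 14 without single libraries.

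The number of genes whose imeglimin response differs between BAT and liver, 25 as reported, was 9 with the number as a fixed replicate block, 9 with median-ratio scaling, 147 with library weights per tissue, 2 with a separate spread per tissue and 4 with the 20 libraries of the 2 tissues. It was 68 without sWAT replicate 88, 0 without BAT replicates 79 and 94, and 0 (without 80) to 193 (without 88) when a number was left out in all tissues. The number of genes whose imeglimin response differs between BAT and sWAT, 306 as reported, was 202 with a pseudocount of 0.10, 78 with median-ratio scaling, 81 with library weights, 55 with separate spreads, 53 with the 20 libraries, 521 without sWAT replicate 88, 60 without BAT replicates 79 and 94, and 23 (without 91) to 867 (without 88). The number of genes whose imeglimin response differs between liver and sWAT, 19 as reported, was 2 with a pseudocount of 0.10, 6 with a mean of at least 5 TPM, 12 with median-ratio scaling, 0 with separate spreads, 0 with the 20 libraries, 35 without sWAT replicate 88, 12 without BAT replicates 79 and 94, and 0 (without 80, 89 or 91) to 89 (without 86). The labels do not say that a number names an animal. Correlations of same-numbered libraries had medians of 0.0978 for BAT and liver, 0.156 for BAT and sWAT and 0.0728 for liver and sWAT, and were over 0.1 for 4, 6 and 3 of 10 numbers, a hint of pairing that did not hold for every number. By best match, 6 of 10 numbers in BAT matched their own number best in liver, 3 in sWAT, and 2 of 10 between liver and sWAT, and the consensus correlation was 0.0395.

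The correlation of log2 fold changes between BAT and liver turned to -0.0189 with Spearman's rho and ranged from -0.0110 to 0.149 without single numbers. The correlation of log2 fold changes between BAT and sWAT ranged from 0.1002 to 0.289, and the correlation of log2 fold changes between liver and sWAT from 0.0842 to 0.162.

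With median-ratio scaling the signs of 4 genes in BAT turned, to 0.0882 for Ucp1, 0.13 for Adrb3, 0.0472 for Scp2 and 0.0196 for Cyp27a1. Signs also turned without single libraries for genes that had not passed. The ranges were -0.12 to 0.0180 for Ucp1 in BAT, -0.0827 to 0.0358 for the log2 fold change of Adrb3 in BAT, -0.45 to 0.12 for Dio2, -0.18 to 0.13 for Prdm16, -0.22 to 0.0544 for Lbp and -0.00347 to 0.58 for the log2 fold change of Mt1 in BAT. They were -0.28 to 0.13 for Cyp4a14 in liver, -0.25 to 0.0506 for the log2 fold change of Cyp8b1 in liver, -0.54 to 0.22 for G6pc in liver and -0.25 to 0.27 for Pck1 in liver, and -0.21 to 0.0790 for the log2 fold change of Adipoq in sWAT and -0.28 to 0.56 for Tnf in sWAT. Of 67 named results in BAT, 51 kept sign and side of the threshold with median-ratio scaling and 12 no longer passed. In sWAT 59 of 60 did and in liver 37 of 37.

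Other splits of the 10 libraries into groups of 5 were run, 100 including the real one. For genes changed by imeglimin in BAT, 2 of 100 splits gave as many calls as the real 99, and the highest other gave 189. For the lipogenesis members adjusted over the list alone, 3 gave as many as the real 16 (highest other 17). For genes changed in sWAT, 1 split, the real one, gave 2 (highest other 1). At the level of 1 in 20, chance can be excluded for the gene counts of BAT and sWAT from TPM as deposited. In sWAT this rests on 2 genes against 1 in the highest other split. Each count fell to 0 without any of 6 of the 10 libraries. The splits were not run with median-ratio scaling, under which fewer genes passed in both tissues. They therefore do not tell changes of single genes from a shift in scale between the groups. In every tissue the HFD libraries carry numbers from 75 to 83 and the imeglimin libraries numbers from 86 to 94. Excluding chance therefore does not tell imeglimin from anything else that follows the order of the numbers. The lipogenesis list was singled out after the data were seen, its share does not allow for that choice, and its list mean had an exact permutation p of 0.0694 adjusted over the lists. Before adjustment that p was 0.00794, the smallest possible. The adjusted value thus depends on how many lists reach this floor and cannot measure the size of the fall. For genes changed in liver all 100 gave at least the real 0 (highest other 63). For the lists, 49 of 100 splits in BAT gave as many calls as the real 13 (highest other 21), 90 in liver as many as the real 5 (17) and 93 in sWAT as many as the real 11 (23), so chance cannot be excluded for the numbers of lists. For the differences between tissues, 2 splits gave as many as the real 25 between BAT and liver (highest other 32), 1 as many as the real 306 between BAT and sWAT (176), and 2 as many as the real 19 between liver and sWAT (24).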

Other observations

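The genes in this part were singled out after their values were seen, and their p-values are those of limma over all genes or over a list. No list of glycogen or glycerol phosphate genes was tested. In BAT Gbe1, the glycogen branching enzyme gene, fell by 0.66 (SE 0.124, adjusted p = 0.0446), from 85.1 ± 7.89 to 54.1 ± 10.7 TPM (SD, n = 5). The glycerol phosphate dehydrogenase genes Gpd1 and Gpd2 fell by 0.59 and 0.75 (adjusted p = 0.0485 for both). Pygl (-0.87, adjusted p = 0.0501) and the glycogen synthase gene Gys2 (-0.54, 0.0606) did not pass. Deptor fell by 1.02 (adjusted p = 0.0291), from 79.5 ± 11.99 to 38.9 ± 6.50 TPM, and Ccdc3, which encodes a secreted protein of adipocytes, by 0.59 (0.0291).

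Among adipocyte genes, Cfd was higher over its list alone in both fat depots, at 1.05 in BAT (list adjusted p = 0.0276) and 1.41 in sWAT (list adjusted p = 7.5e-04), and passed over all genes in neither. Lep and Npr3 were lower over the list alone in BAT (-0.78 and -0.94, list adjusted p = 0.0204 and 0.0186). In sWAT the adrenergic receptor gene Adrb3 (1.16), Nnat (0.90) and Vnn1 (1.27) were higher over their lists alone, with list adjusted p-values of 0.0179, 0.0150 and 0.0453, and none passed over all genes. Of 18 circadian genes measured in BAT, 10 had negative and 8 positive changes, with a median of -0.05. That list was not called (camera adjusted p = 0.325, adjusted p = 0.867 with an estimated correlation). Over the list alone 4 were lower and 0 higher, among the lower ones Clock (-0.26), Arntl (-0.49) and Cry1 (-0.59). None of the 18 passed over all genes in limma's test.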
